A study of Mus musculus with 5 samples.

How the data were processed

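White abdominal fat of male ob/ob mice was profiled by stranded total RNA sequencing after removal of ribosomal RNA, per the labels' protocols. The submitters' processing notes name BWA 0.7.3 and the mouse genome build mm9. The counting program, its strand setting and its treatment of reads with several matches are not given in the sources used here, so near-identical paralogs and overlapping or antisense genes are uncertain. Samples were grouped by their labels into 2 control and 3 MS417 libraries.

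The authors deposited 3 tables, each of a pair of libraries, with 1 line per RefSeq transcript. Per the file headers and values, the deposited counts are whole-number reads per transcript. The authors also deposited log2 values of those counts after scaling by 1 factor per library and table, and the log2 ratio of the first-named over the second-named library. In each table the larger scaled value of every line was at least 100, so transcripts low in both libraries of a pair are not listed, and a gene had to be listed in all 3 tables to be tested. Blank counts, 6, 7 and 0 in the tables, were read as 0. Control 1 stands in 2 tables with equal counts and entered each test once. Of 21285 transcripts in any table, 19275 were in all 3, and they belonged to 14042 genes. For the 3141 genes with several lines, the transcript with the highest mean count was kept, and sums per gene and separate transcripts were tried as alternatives. A spreadsheet had turned 44 gene symbols into dates, and these were restored through the gene identifier. Coordinates are those of the tables (mm9), with starts counted from 1.

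Counts over the tested genes came to between 40276407 and 46367953 per library, and the 10 most abundant genes took between 7.13% and 9.78% of them. Counting error is small at this depth for genes far over 1 CPM, where the number of libraries limits the precision. For genes near 1 CPM, such as Csf3 and Ccbp2 in the MS417 libraries, counting error adds to the spread. The common biological coefficient of variation of the labelled comparison was 26.1%.

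Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, default low-count filter) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are CPM, counts scaled to the library total after TMM. The SE of a log2 fold change is the value implied by the F statistic, the absolute log2 fold change divided by the square root of F. It is rough for genes set by 1 library, such as Adam7 in control 1. Gene lists, 38 in all, covered BET biology, fat and carbohydrate metabolism, fat cells, immune and stromal cell types, neighbouring tissues and stress responses. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01 on log2 CPM with a prior count of 2. Camera with an estimated correlation and fry were alternatives. Other alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals, no filter, a minimum of 5 CPM in 2 libraries, a threshold of 0.1, the replicate number or the set of tables as a block, and each library left out in turn.

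Genes named in the text were to be those past the test. As none passed, the 5 per direction with the smallest p, at a mean of at least 1 CPM and leaving out predicted genes, are named as values. Up to 4 members of each list with the smallest p and a fixed set of 20 BET, lipogenic, adipocyte and macrophage genes could also be named. Members named from the deposited tables are those at least 1.5-fold apart in all 3 tables, a choice made after the values were seen.

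The deposited ratios were described without p-values. The number of genes at least 1.5-fold apart in one direction in all 3 tables was set beside the number that independent tables would share, and beside 50 simulated sets of unchanged libraries drawn with the common dispersion, in which control 1 was shared as in the tables. A list's median ratio was ranked among 10000 random lists matched on mean level in 20 classes. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 was used.

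The edgeR test, camera and the count of genes shared by the 3 tables were tried on simulated data, and the other steps were not. The simulated genes were drawn independently, so the preset correlation of camera was not checked. With the spread of the labelled comparison over 14042 genes, edgeR called 0 of 200 changes of 2-fold and 166 of 200 of 4-fold, with 18 false calls. With the lower quartile of the spread it called 137 and 200 of 200. Of 200 changes of 3-fold between first-named and second-named libraries, 182 were at least 1.5-fold higher in all 3 simulated tables, as were 104 unchanged genes.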

Results

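RNA was sequenced from the white abdominal fat of male ob/ob mice, which lack leptin and become obese, after injection of MS417 or of vehicle (DMSO in saline). MS417 is a small molecule that blocks the bromodomains of the BET proteins BRD2, BRD3 and BRD4, which bind acetylated histones. Animals received 2.5 mg/kg for 15 days from the age of 10 weeks and then 5 mg/kg for 2 weeks, and controls were given the amount of food that treated animals had eaten. There were 2 control libraries and 3 MS417 libraries, and the labels do not state that each library came from its own animal, so p-values measure the spread between these libraries. Counts over 14042 genes came to 45995369 for control 1, 40276407 for control 2, 43796228 for MS417 1, 46367953 for MS417 2 and 40718603 for MS417 3, and levels are given as counts scaled to library size (CPM).

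The first question was which transcripts differed in fat between MS417 and vehicle. By the labels, no gene passed the test, and the genes with the smallest p in each direction are given as values not passing it. Ptx3, a pentraxin made in response to inflammatory cytokines (chromosome 3, 66023809 to 66029728, mm9), stood at 43.8 ± 12.7 CPM in control libraries (SD, n = 2) and 16.6 ± 2.42 in MS417 libraries (SD, n = 3). Its log2 fold change was −1.40 (SE 0.23). Csf3, the granulocyte colony-stimulating factor, was at 3.90 ± 0.947 CPM in controls and 0.98 ± 0.395 in MS417 libraries, a log2 fold change of −1.996 (SE 0.37). Ccbp2, a scavenging chemokine receptor, had a log2 fold change of −1.13 (SE 0.20), the glucose transporter gene Slc2a6 one of −1.05 (SE 0.20) and Spata13 one of −0.85 (SE 0.16). Srxn1, whose product restores oxidised peroxiredoxins, was at 147 ± 39.1 CPM in controls and 281 ± 6.27 in MS417 libraries, a log2 fold change of 0.93 (SE 0.20). The creatine transporter gene Slc6a8 had a log2 fold change of 0.57 (SE 0.15), Htatip2 one of 0.71 (SE 0.19), the biliverdin reductase gene Blvrb one of 0.68 (SE 0.19) and the homeobox gene Lhx8 one of 0.53 (SE 0.15).

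The edgeR quasi-likelihood test called 0 of 14042 genes at an adjusted p under 0.05. The lowest adjusted p was 0.997, and 386 genes had an unadjusted p under 0.05 where 702 would by chance alone. DESeq2 called 3 genes, all lower in MS417 libraries, with 597 at an unadjusted p under 0.05, and limma-voom called 0, with 229. The genes called by DESeq2 were Ptx3 (log2 fold change −1.40, adjusted p 0.0115), Slc2a6 (−1.055, adjusted p 0.028) and Gpx5 (−9.69, adjusted p 0.028). Gpx5, a glutathione peroxidase of the epididymis, stood at 4235 CPM in control 1 and between 2.25 and 2.92 in the other libraries, and it was named after its values were seen. Leaving out either control leaves 1 control library. The spread then comes from the MS417 libraries alone, and a call compares them with that 1 library. Control 1 also held epididymal transcripts such as Gpx5, so genes lower than in control 1 alone can reflect that library and not the drug. Without control 2, edgeR called 239 genes against control 1 alone, 2 higher and 237 lower, with Ptx3 (adjusted p 0.0383) and Srxn1 (0.0452) among them. With control 1 and MS417 3 both left out, a setting chosen after seeing the data, it called 80 against control 2 alone, 9 higher and 71 lower. In simulated libraries with the spread of the labelled comparison, 0 of 200 changes of 2-fold and 166 of 200 changes of 4-fold were called.

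No transcript of the drug's targets passed the test by label, and Hexim1 and Brd2 differed widely between libraries of one label. Hexim1, an inhibitor of the elongation factor P-TEFb whose transcript BET inhibitors raise in many cell types (chromosome 11, 102977639 to 102981038, mm9), was at 114 CPM in control 1 and 108 in MS417 3. It was at 23.8 in control 2, 25.7 in MS417 1 and 23.4 in MS417 2. Brd2 (chromosome 17, 34248964 to 34259552) was at 326 and 367 CPM in control 1 and MS417 3 and between 121 and 136 in the other libraries. The log2 fold change of MS417 over control was −0.40 (SE 0.90) for Hexim1, −0.10 (SE 0.63) for Brd2, −0.25 (SE 0.18) for Brd3 and −0.16 (SE 0.20) for Brd4. None of these passed the edgeR test, and both Hexim1 and Brd2 turned positive without control 1, to 1.13 and 0.79, while Brd3 and Brd4 were then at −0.11 and −0.05. The proto-oncogene Myc, a known BET target in blood cancers, had a log2 fold change of 0.10 (SE 0.29).

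The series title names synthesis of carbohydrate and lipid, and Fasn and Acly divided the libraries as Hexim1 did, though most members of the lipogenesis list were not 1.5-fold apart in all tables. Fasn, the fatty acid synthase gene (chromosome 11, 120667272 to 120685861), stood at 4715 CPM in control 1 and 5244 in MS417 3, against 1603 in control 2, 1306 in MS417 1 and 1351 in MS417 2. Acly, which makes cytosolic acetyl-CoA, stood at 1590 and 1411 CPM in control 1 and MS417 3 and between 382 and 477 in the others. By label, the log2 fold change was −0.26 (SE 0.78) for Fasn, −0.47 (SE 0.75) for Acly and −0.15 (SE 0.58) for the acetyl-CoA carboxylase gene Acaca, and without control 1 these were 0.72, 0.64 and 0.37. The desaturase gene Scd1 had 0.02 (SE 0.44), and the lipogenic regulators Srebf1 and Mlxipl had −0.45 (SE 0.24) and 0.11 (SE 0.30), of which Srebf1 was at −0.02 without control 1. None passed the edgeR test. Of the 20 lipogenesis genes measured, 14 had a negative fold change, and the list was not called by camera (median −0.14, adjusted p 0.228). Without MS417 3 it was called lower (median −0.49, adjusted p 0.0016), as it was with the replicate number as a block (median −0.46, adjusted p 0.000305). Both calls rest on the preset correlation of 0.01, whereas the estimate for this list over all 5 libraries was 0.397, with which it was not called (adjusted p 0.894).

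No adipocyte gene of the fixed set passed the edgeR test. The log2 fold change was 0.03 (SE 0.18) for Pparg and 0.17 (SE 0.22) for Cebpa, the main regulators of fat cell differentiation. It was 0.08 (SE 0.22) for the adiponectin gene Adipoq, 0.03 (SE 0.39) for Lep, 0.03 (SE 0.47) for the insulin-regulated glucose transporter gene Slc2a4 and 0.24 (SE 0.23) for the gluconeogenic and glyceroneogenic enzyme gene Pck1, the last at 0.12 without control 1 and 0.03 without MS417 3. Scaling by library totals turned the values of Pparg, Lep, Slc2a4 and Scd1 negative. Ucp1, the uncoupling protein of brown fat, was not among the genes listed in all tables.

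**Figure D1:**
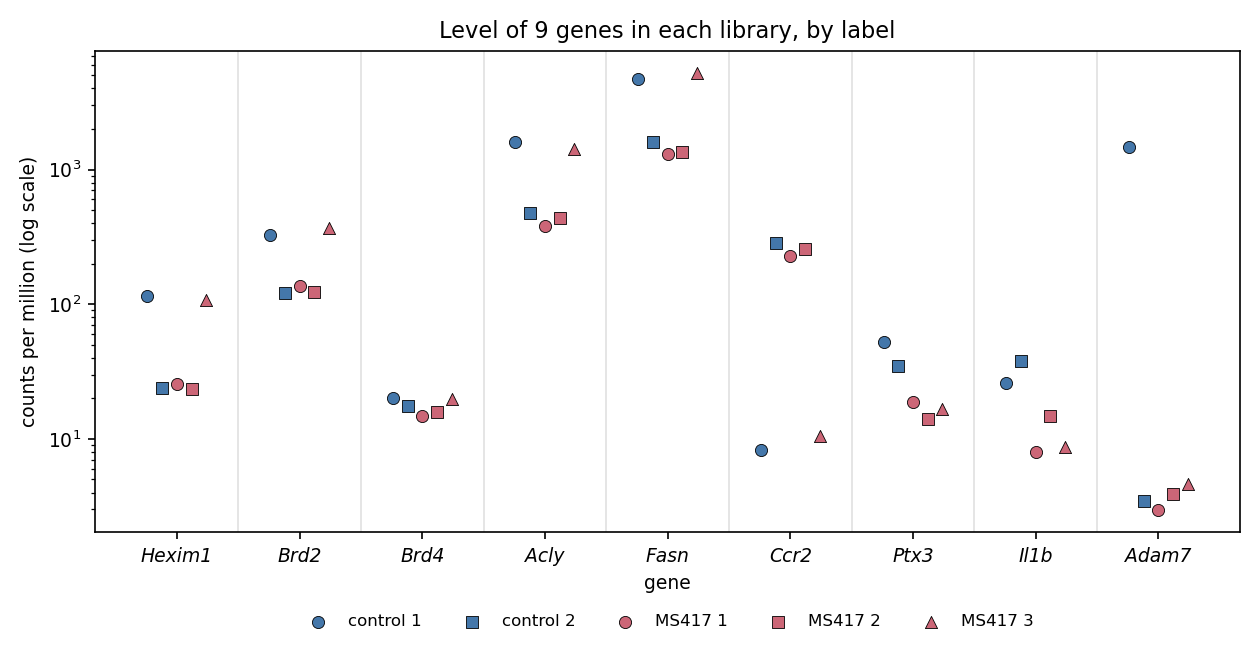
CPM, counts scaled to library size (log scale), of 9 genes in each of the 5 libraries, with colour for the labelled group and symbol for the replicate number. Hexim1, Brd2, Acly and Fasn were highest in control 1 and MS417 3, Ccr2 was lowest there, Ptx3 and Il1b were lower in each MS417 library than in both controls, and Adam7 was at 1470 CPM in control 1.

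Of the gene lists fixed before the data were examined, as were the tests and the rule for naming genes, markers of lipid-laden macrophages were higher in libraries labelled MS417. All 15 measured members had a positive fold change, with a median of 0.78 (camera adjusted p 3.77e-09). The call was lost with an estimated correlation (adjusted p = 0.783), and 0 members passed alone, over all genes or adjusted over the list alone. Ctsk, a lysosomal protease, had a log2 fold change of 0.94 (SE 0.28) and Lipa, the lysosomal acid lipase, one of 0.90 (SE 0.32), or 0.51 without control 1. The list kept its call with each library left out, at a median of 0.37 without control 1 (adjusted p 0.00031), 1.31 without control 2 and 0.51 without MS417 1. In the authors' deposited tables the list's median was −1.56 and −1.201 for control 1 over MS417 1 and MS417 2, and −0.24 for MS417 3 over control 2, so that the pair without control 1 ran against the labels. Gpnmb, Mmp12, Itgax and Dcstamp were at least 1.5-fold lower in the first-named library of all 3 tables. The broader macrophage list was also called higher (median 0.21, adjusted p 0.0224, and adjusted p = 0.863 with an estimated correlation). Its pan-macrophage members Emr1 (F4/80) and Cd68 had values of 0.47 (SE 0.32) and 0.57 (SE 0.25), or 0.10 and 0.34 without control 1, and Cd68 0.36 without MS417 1. Without control 1 the macrophage list was called in the opposite direction (median −0.12, adjusted p 0.00799), and without MS417 1 it was no longer called (adjusted p 0.0843). Its median was 0.84 without control 2 and 0.36 without MS417 3.

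Cytokines, chemokines and other NF-κB targets were lower in libraries labelled MS417. In the inflammation list 24 of 27 members had a negative fold change, with a median of −0.52 (camera adjusted p 3.77e-09), which was lost with an estimated correlation (adjusted p = 0.783). Over all genes 0 members passed in edgeR, and 3 passed adjusted over the list alone. These were the genes with the smallest p, Il1b (log2 fold change −1.61, SE 0.33), the neutrophil chemokine gene Cxcl1 (−1.24, SE 0.26) and the adhesion molecule gene Icam1 (−0.85, SE 0.18). Il1b was at 31.9 ± 8.42 CPM in controls (SD, n = 2) and 10.5 ± 3.71 in MS417 libraries (SD, n = 3). Without control 2 the list was no longer called (median −0.15, adjusted p 0.193), while Cxcl1 and Icam1 then passed over all genes (adjusted p 0.0453 and 0.0437) against control 1 as the single control library, where both were at their highest. Some neutrophil transcripts lay lower too, as values not passing the test, with a log2 fold change of −1.36 (SE 0.37) for S100a9 and −0.89 (SE 0.22) for Retnlg. Others were less clear, with −0.52 (SE 0.31) for S100a8 and 0.11 (SE 0.20) for Mpo. S100a8 was at 62.5 CPM in control 1 and 125 in control 2, against 65.0, 74.9 and 56.7 in MS417 1, 2 and 3. Csf3r was at 16.0 and 29.8 in the controls, against 13.7, 15.7 and 10.2. The list of neutrophil and mast cell markers was not called (adjusted p 0.223).

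Camera called 14 of the 38 lists, 9 higher and 5 lower, and with library totals in place of TMM 11, of which 9 were higher and 2 lower. With an estimated correlation or with fry, 0 were called. Higher lists included oxidative phosphorylation, where 35 of 39 members had a positive fold change (median 0.15, adjusted p 0.000154, and adjusted p = 0.783 with an estimated correlation). The median was 0.08 without control 1 (adjusted p 0.0331) and 0.23 without control 2 (adjusted p 0.00581), and the call was lost with the replicate number as a block (adjusted p 0.0545). Its member Sdhb, a subunit of complex II, had a log2 fold change of 0.27 (SE 0.13). Fatty acid oxidation genes had a median of 0.18 (adjusted p 0.00504) with Cpt1a, the carnitine transfer enzyme, at 0.34 (SE 0.16). Proliferation genes had a median of 0.31 (adjusted p 2.54e-07) with the replication clamp gene Pcna at 0.40 (SE 0.19), and extracellular matrix genes a median of 0.20 (adjusted p 0.00343). For these 3 lists the adjusted p was 0.783 with an estimated correlation, and without control 1 it was 0.716, 0.826 and 0.867 (medians 0.04, 0.02 and 0.05), with Cpt1a at 0.18 and Pcna at 0.21. Without control 2 the medians of fatty acid oxidation and proliferation were 0.31 and 0.76, and without MS417 1 that of extracellular matrix was 0.13. The fatty acid oxidation list was also not called without MS417 3 (adjusted p 0.071).

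Smaller differences were called in lists of glycolysis (median 0.07, adjusted p 0.0262), cholesterol synthesis (0.12, adjusted p 0.0224) and endothelial cells (0.14, adjusted p 0.017). With an estimated correlation their adjusted p was 0.783, 0.783 and 0.854. The glycolytic enzyme gene Pgk1 had a log2 fold change of 0.40 (SE 0.15). Lower lists were those of smooth muscle and pericytes (median −0.50, adjusted p 0.00135), B and plasma cells (−0.33, adjusted p 0.0262), stromal progenitors (−0.09, adjusted p 0.0262) and liver (−1.31, adjusted p 0.017). With an estimated correlation the first 3 had an adjusted p of 0.783 and the liver list one of 0.795. Acta2, the smooth muscle actin gene, had a log2 fold change of −1.09 (SE 0.35), or −0.49 without control 1, and Pi16, a gene of adventitial progenitors, one of −1.08 (SE 0.29). Each of these 7 lists lost its call without at least 1 library, the smooth muscle list without control 1 (median 0.11, adjusted p 0.727), the glycolysis, cholesterol, B cell and stromal lists without control 2 (0.296, 0.654, 0.961 and 0.654) and the liver list without MS417 3 (0.175). The endothelial list lost it without control 1, control 2 or MS417 3 (0.22, 0.0993 and 0.583), and the glycolysis and stromal lists also without MS417 3 (0.603 and 0.224). The cholesterol list lost it without MS417 2 or MS417 3 (0.0847 and 0.164), and the B cell list also without MS417 1 (0.0843). Without control 1 the liver list had a median of 0.35 (adjusted p 0.172), and without control 2 one of −2.06. Medians also moved where calls were kept, for glycolysis to 0.20 without MS417 1 and 0.13 without MS417 2, for endothelial cells to 0.24 without MS417 1, and for stromal progenitors to −0.26 without control 1, −0.14 without MS417 1 and −0.22 without MS417 2. With library totals the liver, B cell and stromal lists were not called (0.0511, 0.0522 and 0.0524). The remaining lists had an adjusted p between 0.056 and 0.952. Among them, the interferon, T and NK cell, neutrophil and mast cell, thermogenic, glucocorticoid and adipokine lists had a median, a mean and a test that differed in sign.

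Transcripts of other tissues stood apart in control 1. Adam7, a gene of the epididymis, was at 1470 CPM in control 1 and between 2.97 and 4.64 in the other libraries. Lcn5, an epididymal retinoic acid carrier, was at 1192 in control 1 and between 2.27 and 3.40 elsewhere, and Ros1 was at 104 and between 3.24 and 3.89. Alb, the albumin gene of the liver list, was at 626 CPM in control 1, 184 in MS417 2 and between 58.2 and 90.1 in the rest. The log2 fold change by label was −7.59 (SE 2.06) for Adam7, −7.70 (SE 2.05) for Lcn5, −3.85 (SE 1.201) for Ros1 and −1.64 (SE 0.93) for Alb, none past the edgeR test over all genes. Of the 4 measured members of the epididymis and testis list, 3 passed adjusted over the list alone, and without control 1 the values of Adam7, Ros1 and Alb were positive and that of Lcn5 was −0.09.

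Libraries did not group by label. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.993 between MS417 1 and MS417 2 and 0.993 between control 2 and MS417 2, and 0.923 between both controls. MS417 3 correlated at 0.952 with control 1 and between 0.964 and 0.969 with the other libraries. The first principal component held 68% of the variance, with control 1 at −62.5, MS417 3 at −12.9 and the others between 21.9 and 29.4. The second held 21.5%, with MS417 3 at 38.2, control 1 at −16.5 and the others between −8.89 and −6.25. Control 1 and MS417 3 thus also stood apart from each other.

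The authors compared single libraries, control 1 over MS417 1, control 1 over MS417 2 and MS417 3 over control 2, so these tables have no replicate check and no p-value is given for them. Read as MS417 over control, few genes moved one way in all 3. In the authors' deposited tables, of 14042 genes 164 differed by at least 1.5-fold in one direction in each pair, 4 higher and 160 lower with MS417. Independent tables with the same numbers of genes would share 49.0 higher and 281 lower, and simulated unchanged libraries gave a mean of 215 in all. The simulated ratios were centred on 0, whereas the deposited ones had medians of 0.17, 0.10 and −0.09. Their spread was that of the labelled comparison, which includes the differences between libraries of one label. The simulated counts, here and by column order, are thus a rough guide only. In the inflammation list 3 of 27 members were lower in all pairs and 0 higher, while 6 others were at least 1.5-fold lower in the first-named library of all 3 tables, against the labels in the pairs with control 1. Members lower by label in all pairs numbered 3 of 16 in the stromal progenitor list, where Icam1 is also counted among the 3 of the inflammation list. In the mesothelial list they numbered 3 of 11, the keratin genes Krt8, Krt18 and Krt19. Krt18 stood at 138 CPM in control 1, 3.71 in control 2 and between 1.41 and 11.1 in MS417 libraries. It was also among the genes over 10-fold above both MS417 1 and MS417 2 in control 1. Of the 15 BET genes and the 20 lipogenesis genes, 0 moved one way by label in all pairs.

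Read by the order of their columns, first-named over second-named library, the same deposited tables shared 1093 genes, 287 higher and 806 lower, where independent tables would share 72.3 and 190 and simulated unchanged libraries 211 in all. This reading was chosen after the values were seen. Of the BET list, Hexim1, Brd2, the neuroserpin gene Serpini1 and the linker histone gene Hist1h1c were higher and the chemokine receptor gene Ccr2 lower in all 3. The authors' deposited log2 ratios of Hexim1 were 2.26, 2.35 and 2.07, and those of Ccr2 were −4.67, −4.89 and −4.85. In the lipogenesis list Acly, Acaca, Fasn, Scd2, Acss2, Thrsp and Aacs were higher in all tables and the oxysterol receptor gene Nr1h3 was lower. The list's median in the authors' deposited tables was 0.91, 0.73 and 0.46, each at the 100 percentile of 10000 random lists of like expression.

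Macrophage, T and NK cell and interferon-response transcripts ran the other way in the authors' deposited tables. Of 22 macrophage genes 9 were at least 1.5-fold lower in the first-named library of all 3, among them the integrin genes Itgam and Itgax, and the medians were −1.05, −0.73 and −0.59. Of 14 genes of T and NK cells 8 were lower, with Cd8a at −1.64, −1.10 and −2.27 and the granzyme gene Gzmb at −2.21, −1.91 and −2.54. Of 20 interferon-response genes 9 were lower, including Stat1 and Ifit3. The B and plasma cell list, with medians of 0.48, 0.21 and −0.24, and the neutrophil and mast cell list, with 0.07, −0.20 and −1.25, did not share that direction. The median of the inflammation list was 0.15, 0.19 and −1.25, at the 65.9, 89.3 and 0 percentile of random lists. Read as MS417 over control, it was below 0 in all 3 pairs, but the deposited ratios were not centred on 0. The median ratio over all lines was 0.17, 0.10 and −0.09 in these tables. Only in MS417 3 over control 2 was the inflammation list far from its table's median. Between tables with no library in common, the correlation of log2 ratios across genes was 0.471 for control 1 over MS417 1 against MS417 3 over control 2 and 0.519 for control 1 over MS417 2 against it, with no p-value because genes are not independent.

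**Figure D2:**
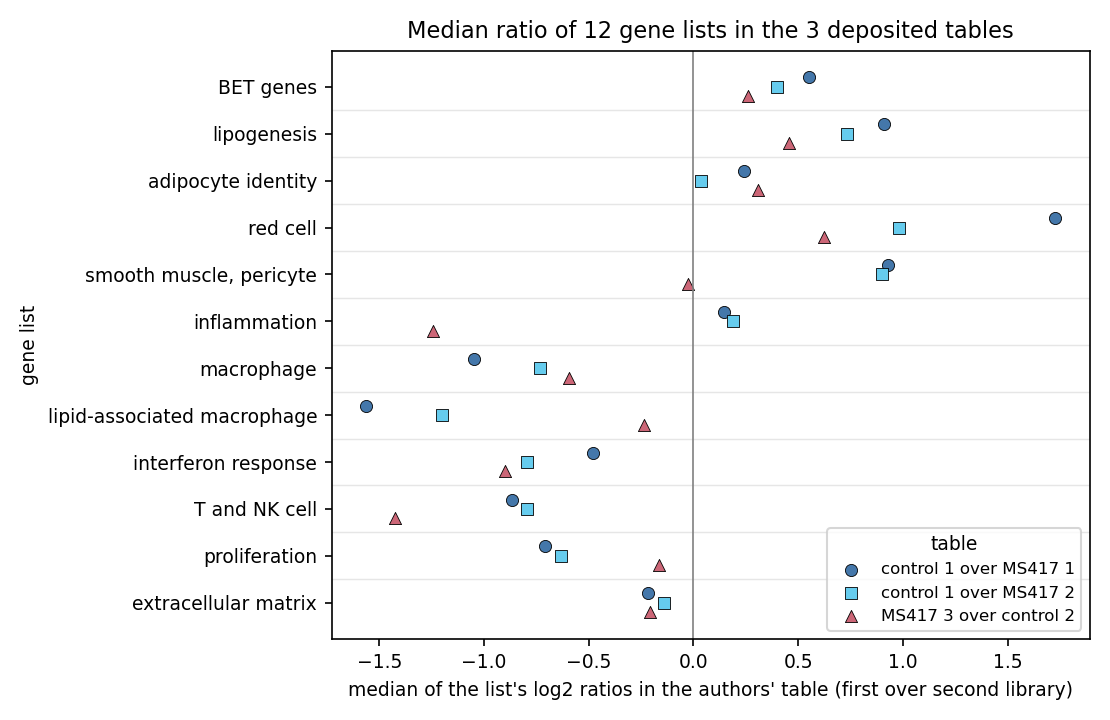
Median log2 ratio, first-named over second-named library, of 12 gene lists (vertical axis) in each of the 3 deposited tables, 1 point per table. The BET, lipogenesis and red cell lists lay above 0 and the macrophage, interferon and T and NK cell lists below 0 in all 3 tables, while the inflammation list lay at −1.25 in the table of MS417 3 over control 2 and above 0 in the other 2.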

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

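All tests of explanation in this part were chosen after the results were seen. Groups of 2 and 3 libraries are too small for a test of single libraries against their group. A signal outside the comparisons appeared in the transcripts that the table without control 1 does not list. In control 1, 222 genes were over 10-fold above both MS417 1 and MS417 2 in the authors' deposited ratios, and 190 of them were not listed in the table of MS417 3 over control 2. The 222 genes together took 2.66% of the counts of control 1, against 0.035% in MS417 1 and 0.037% in MS417 2. The most abundant of the 190 were Slc38a5 (63502 counts against 38 and 53), Cuzd1 (48113 against 19 and 28), Spink5 (39309 against 67 and 85) and the defensin gene Defb20 (37407 against 9 and 11), named after their values were seen.

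A candidate explanation is epididymal tissue in the sample labelled control 1, since abdominal fat of male mice includes the pad along the epididymis. The listed epididymal members of the list fixed in advance were Adam7, Lcn5, Crisp1, Defb42, Spink11 and Ros1. All 6 were over 10-fold higher in control 1 than in both libraries paired with it. For Crisp1, Defb42 and Spink11 the direction, though not the size, was set by the listing rule. They were too low in MS417 1 and MS417 2 to be listed without a higher value in control 1. Adam7, Lcn5 and Ros1 were listed in every table, so their direction was not set in this way. Of the 18 genes of the epididymis and testis list, 8 were listed in any table, and the others could not be compared. Defb42 had 11975 counts against 16 and 15, and Adam7 70992 against 128 and 183. Star, a gene of steroid-making cells in that list, had 691 counts in control 1 against 715 and 971, and Cyp17a1, another, had 124 against 59 and 79. The design names no biological difference for this library other than its treatment label, which control 2 shares, with 140 counts of Adam7.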

How the results depend on the processing

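Settings chosen after seeing the data were leaving out control 1 and MS417 3 together, leaving out a deposited table, leaving out genes high in control 1 and reading the tables by column order. With edgeR, the count of 0 genes by label (386 at an unadjusted p under 0.05) was 0 under DESeq2 size factors, library totals, a minimum of 5 CPM, a threshold of 0.1, summed or separate transcripts and the table-set block, and 0 under limma-voom (229). The default filter removed no gene, so leaving it out tests nothing. The count was 3 under DESeq2 (597), 0 to 239 when 1 library was left out and 80 without control 1 and MS417 3; 239 and 80 come from a single control library. The replicate block gave 0 genes (183) and 10 lists. The labels tie no number to an animal, and with 2 controls the deviations from their mean are opposite, so pairing could not be tested. The 14 called lists became 0 with an estimated correlation, 0 with fry and 9 to 20 with 1 library left out, and 12 without control 1 and MS417 3. Of the 3 BET genes 0 passed in each setting run for them. The 164 genes shared by label became 31 at 2-fold and 3514 without the table of MS417 3 over control 2, where fewer tables must share a direction. By column order 1093 became 401 and 3514, and 1091 without genes over 10-fold higher in control 1.

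Values turned sign as follows, the cause not tested. Under limma-voom Scd1 was −0.085, Lep −0.046 and Slc2a4 −0.105. With library totals Scd1 was −0.067, Pparg −0.045, Lep −0.059 and Slc2a4 −0.066. With the replicate block Mlxipl was −0.155, Scd1 −0.481, Pparg −0.068, Cebpa −0.020, Adipoq −0.014, Lep −0.392 and Slc2a4 −0.550. With the table-set block Scd1 was −0.009 and Slc2a4 −0.055. With 1 library left out, ranges were −8.58 to 0.155 for Adam7, −4.80 to 0.203 for Ros1, −2.50 to 0.820 for Alb, −0.800 to 0.785 for Brd2, −1.505 to 1.13 for Hexim1 and −0.203 to 0.476 for Myc. They were −0.185 to 0.386 for Mlxipl, −1.345 to 0.642 for Acly, −0.891 to 0.369 for Acaca, −1.26 to 0.716 for Fasn and −0.484 to 0.248 for Scd1. They were −0.065 to 0.141 for Pparg, −0.023 to 0.294 for Cebpa, −0.125 to 0.330 for Adipoq, −0.398 to 0.248 for Lep and −0.576 to 0.285 for Slc2a4. Medians ranged from −0.122 to 0.839 for the macrophage list, −2.06 to 0.354 for the liver list, −0.661 to 0.106 for the smooth muscle list, −0.300 to 0.197 for the BET list and −0.490 to 0.159 for the lipogenesis list. With library totals the glycolysis median was −0.004, its call kept. Of the other values of named genes, 583 kept direction and side of the threshold (those without the filter could not differ) and 9 passed it. Of those of lists, 98 kept their side of the threshold, sign changes above included, 58 lost the call and 2 gained it.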

Other observations

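The tests of explanation in this part were chosen after the results were seen, except the splits of the libraries for the inflammation list. In the authors' deposited tables, 4 of 6 red cell genes were higher in the first-named library of all 3, and 4 of 11 genes of the neutrophil and mast cell list were lower. The latter were mast cell protease genes, picked out after their values were seen, with log2 ratios of −3.78, −3.39 and −1.79 for Cpa3 and −5.22, −4.51 and −1.73 for Mcpt4, while the mast cell marker Kit had 0.17, 0.56 and −0.03. Hba-a1, an alpha-globin gene, was higher, with 1.91, 1.08 and 0.60, as was the haem synthesis gene Alas2 with 1.78, 1.04 and 0.65. Of the 25 adipocyte genes, Slc2a4, Car3, Rbp4 and Lipe were higher in all tables and 0 were lower. Pdk4, a kinase that restrains glucose oxidation, was lower with −2.04, −1.94 and −0.91. The genes with the largest shared ratios, named after their values were seen, included Gpr137c and Ehd3 on the higher side and the receptor genes Ccr5, Ccr1 and Itgad on the lower side.

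By the labels edgeR called 0 genes with 386 at an unadjusted p under 0.05 (DESeq2 3, limma-voom 0), while 1 of the 10 splits of the 5 libraries into 2 and 3, control 1 and MS417 3 against the rest, called 1467. The 10 splits are too few for a share under 0.05, and a split with 1467 calls points to a structure of the samples. Epididymal tissue in control 1 is argued against as the whole of this structure, since the table without that library shared 4.16 times as many genes with the other tables as independent tables would. An exchange of library labels between the groups and a difference in feeding between animals stay open and cannot be told apart. Controls were given the amount of food that treated animals had eaten, which limits a difference in amount between the groups. It does not exclude a difference between animals of one group, such as control 1 against control 2. By the order of the columns 5 of 15 BET genes and 8 of 20 lipogenesis genes were 1.5-fold apart one way in all 3 tables. These shares exceeded that of all genes (1093 of 14042), and the BET medians lay at the 99.8, 99.4 and 99.99 percentile of random lists. Larger shares of other lists were apart too, among them the interferon list (9 of 20), the T and NK cell list (8 of 14) and the red cell list (4 of 6). The counts take both directions together, and 1 source could move several lists, so a comparison between lists cannot name the source. These counts bear out the division and not its source.

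If labels were exchanged, the tables do not say how. The values would be met if control 1 were a treated library and MS417 1 and MS417 2 were vehicle libraries, or if control 2 and MS417 3 had changed places, and the direction of every ratio differs between these versions. Hexim1, whose transcript BET inhibitors raise in many cell types, would be higher with the drug in the first version and lower in the second. The second version would keep 2 control and 3 MS417 libraries, as labelled, and the first would not. The tables do not decide between them. Apart from the splits of the 5 libraries into 2 and 3, no library was moved to another group in any test.

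The lower inflammation list in libraries labelled MS417 is the second pattern. Of the 10 splits, 2 gave a median as far from 0, the labels with −0.44 on mean log2 values and the split of MS417 2 and MS417 3 from the rest with 0.55, and 10 splits are too few for a share under 0.05. The median stayed below 0 without each of the 5 libraries, but it was −0.15 without control 2, where the call was lost (adjusted p 0.193), so the call and its size depended on that library and the direction without it stays open. Fewer neutrophils in these libraries may account for part of it, as the 6 neutrophil members of the fixed list had a median log2 fold change of −0.71. Against this, Mpo was at 0.11, and S100a8 was no higher in control 1 (62.5 CPM) than in MS417 1 (65.0) or MS417 2 (74.9). The doubt about the labels applies to this pattern too.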
